A study of Mus musculus with 2 samples.

How the data were processed

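Dissociated cells of the mouse dentate gyrus at postnatal day 5 were profiled by 10x Genomics 3' single-cell RNA sequencing, with 1 control (wild type) library and 1 Setdb1_cKO library. Per the labels' protocols, tissue was dissociated enzymatically, about 20000 cells were loaded and 10000 cells were aimed for per library. The deposited matrices hold UMI counts per gene and barcode, whole numbers that were not normalised, per the file headers and values. The counts were made with Cell Ranger 7.1.0, per the file headers and the submitters' processing notes, and the genome build was mm10, per the submitters' processing notes, which also name Seurat. The annotation release, the treatment of intronic reads and the cell calling settings are not given in the sources used here. The lowest barcode held 500 UMIs in both libraries, so barcodes of low depth had been removed before deposit. The number of animals behind each library is not given in the sources used here either. Coordinates and gene types came from GENCODE vM21 on GRCm38, the same assembly as mm10, by Ensembl gene identifier: 32235 of 32285 identifiers matched.

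Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. In the control library 1723 barcodes fell short on UMIs, 1108 on genes and 2173 exceeded the mitochondrial limit, and 11414 passed; in the Setdb1_cKO library the numbers were 974, 630, 1509 and 9956. Doublets were called per library with Scrublet (scanpy 1.11.5, expected rate 8%), which marked 724 of 13078 scored control barcodes (5.54%) and 711 of 11246 Setdb1_cKO barcodes (6.32%). After removal of 615 and 611 doublets that had passed the filters, 10799 and 9345 cells with 72560661 and 76109907 UMIs were kept. Kept cells had medians of 2524 and 2757 genes, and the median mitochondrial share over all barcodes was 4.33% and 4.61%. Cells of both libraries were clustered together on 2000 variable genes, 30 principal components and shared neighbours among the nearest 20 cells with Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0).

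Clusters were named from marker genes of 19 cell types. A cluster took the type with most markers among its 10 leading genes by fold, then the highest mean marker score. It stayed unnamed when that score lay over 0.2 below the best one, when no marker led and the score was under 0.5 or within 0.2 of the next type, when under 3 markers reached 20 CPM, when an erythroid cluster had under 50% haemoglobin UMIs, or when its depth was under 1/3 of its library's median with no marker leading. The markers, the gene lists, the filters, the alternatives and the rule for naming genes were set before the data were examined. The naming thresholds were set after a first clustering had been seen. They left out 3 clusters: one led by Olig2 and Egfr (414 control and 235 Setdb1_cKO cells), one of low depth (332 and 139 cells) and one with haemoglobin and neuronal genes (42 and 196 cells).

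Within each class, UMIs were summed per library and scaled to CPM by the class total. Summed UMIs in control and Setdb1_cKO were 8472911 and 8061720 in radial glia (12516 genes measured), 14846761 and 10114190 in intermediate progenitors (12667), 19247443 and 20899245 in neuroblasts (13355), 524086 and 5776758 in granule neurons (10250) and 8585517 and 5675913 in astrocytes (12053). A gene counted as measured with at least 30 UMIs over both libraries. Ratios carry exact conditional Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Because each genotype had 1 library, no p-value or number of changed genes was computed, and differences are between these libraries, not between genotypes. A ratio against 0 UMIs was bounded with 3 counts over the class or library. Log2 ratios used a pseudocount of 0.5 UMI. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs.

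In each main class, measured genes with at least 20 CPM in the higher library were ranked by the bound of the ratio's interval nearest to 1. The 12 highest and 12 lowest could be named, and mitochondrial, haemoglobin, ribosomal protein and sex-linked genes among them were then left out without replacement, since they are given as lists. Further named genes were Setdb1, at most 6 members per list and class with a ratio of at least 2-fold and an interval that excluded 1, taken by level, and genes at least 2-fold apart the same way in all 5 main classes, with sex-linked genes counted apart. Single genes that led the clusters of a class are not given as results of that class, apart from Calb1 as a statement about its cluster. Lists and the cycling shares could hold such genes. The 22 lists were clustered protocadherins, H3K9 methylation and partner genes, germline genes, interferon response genes, imprinted genes, S phase genes, G2/M genes, p53 target genes, immediate early and heat shock genes, unfolded protein and integrated stress response genes, glial fate genes, neuronal fate transcription factors, granule neuron maturation genes, quiescence and niche signalling genes, Wnt and Shh signalling genes, cholesterol synthesis genes, sex-linked genes, haemoglobin genes, reactive glia and complement genes, mitochondrial genes, ribosomal protein genes and zinc finger protein genes. For each list with at least 3 measured members, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and its range was taken over 1000 redraws of Poisson counts. Members at least 1.5-fold apart were counted in each direction.

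The ratios and lists were tested on simulated Poisson counts with 200 changed genes. The draws held no variation between cells, animals or dissections, so the shares below are not error rates of the real comparison. For radial glia (12529 genes) the interval excluded 1 in the right direction for 95.0% of genes changed 2-fold and 100% changed 4-fold, and excluded 1 for 4.27% of unchanged genes. For granule neurons (10234 genes) these shares were 61.0%, 93.0% and 3.29%. Alternatives covered looser and stricter cell filters, doublets kept, Leiden resolutions of 0.6 and 2.0, clustering without sex-linked, mitochondrial, haemoglobin, ribosomal, immediate early and cell cycle genes, TMM factors from edgeR 4.0.16, a median-of-ratios factor, totals without mitochondrial, haemoglobin and ribosomal protein genes, averaging over cells, other UMI minimums and other thinning. Chosen after the data had been seen were each library clustered and named alone, the early and late neuroblast clusters taken separately, astrocytes without a small Gfap-rich cluster, granule neurons without the 7 control cells named pyramidal or mossy neurons under separate clustering, unnamed clusters left out of the denominator, and the sum of all listed germline genes, with and without the member of highest level. Transposable elements, which Setdb1 silences, were not analysed here, and a test of microglia markers in astrocytes, set before its result was seen, is not reported here. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.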

Results

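Single-cell RNA sequencing was used to compare the dentate gyrus of a control (wild type) and a Setdb1_cKO library, both taken at postnatal day 5. The dentate gyrus is the part of the hippocampus in which radial glia, through intermediate progenitors and neuroblasts, give rise to granule neurons and to astrocytes. Setdb1 encodes a methyltransferase that places the repressive mark H3K9 trimethylation, and cKO stands for a conditional knockout of this gene. The question, as the title of the series states it, was how Setdb1 bears on keeping a cell state and on the choice of cell fate. Each genotype had 1 library, so no difference below has a replicate check, no test between genotypes was made, and all intervals cover counting error only. The control library held 14397 barcodes and 82393428 unique molecular identifiers (UMIs), and the Setdb1_cKO library held 12060 barcodes and 87845965 UMIs. After filtering, 10799 control cells with a median of 5933 UMIs and 9345 Setdb1_cKO cells with a median of 6981 UMIs were kept. Class names stand for cells like the named type by their marker genes. Values are Setdb1_cKO to control ratios of UMI counts summed over the cells of a class and scaled to the class total (CPM), with the 95% exact interval in parentheses.

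Setdb1 itself (ENSMUSG00000015697, chromosome 3, 95323525 to 95357202, reverse strand, mm10) was lower in the Setdb1_cKO library in the neural classes of the dentate lineage. Over all kept cells it was at 42.8 CPM in control (3104 UMIs) and 20.4 CPM in Setdb1_cKO (1552 UMIs), a ratio of 0.477 (0.448 to 0.507). The ratio was 0.303 (0.248 to 0.367) in radial glia, 0.357 (0.276 to 0.457) in astrocytes, 0.455 (0.388 to 0.533) in intermediate progenitors, 0.531 (0.472 to 0.597) in neuroblasts and 0.548 (0.354 to 0.883) in granule neurons. Pyramidal or mossy neurons were at 0.319 (0.251 to 0.405) and Cajal-Retzius cells, the early reelin neurons of the hippocampal surface, at 0.378 (0.270 to 0.522). In endothelial cells (1.10), fibroblasts (1.08), microglia (0.851), border macrophages (1.35), oligodendrocyte progenitors (1.02) and GABAergic neurons (0.802) the interval included 1. The microglia interval was 0.572 to 1.27. In GABAergic neurons it rested on 11 and 21 UMIs and ran from 0.370 to 1.84, so a decrease like that in neuroblasts stays possible. The deleted exons and the Cre driver are not given in the sources used here. Reads at the 3' end that lie outside the deleted part would check nothing, so the remaining UMIs do not measure the share of cells that kept the gene.

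**Figure D1:**
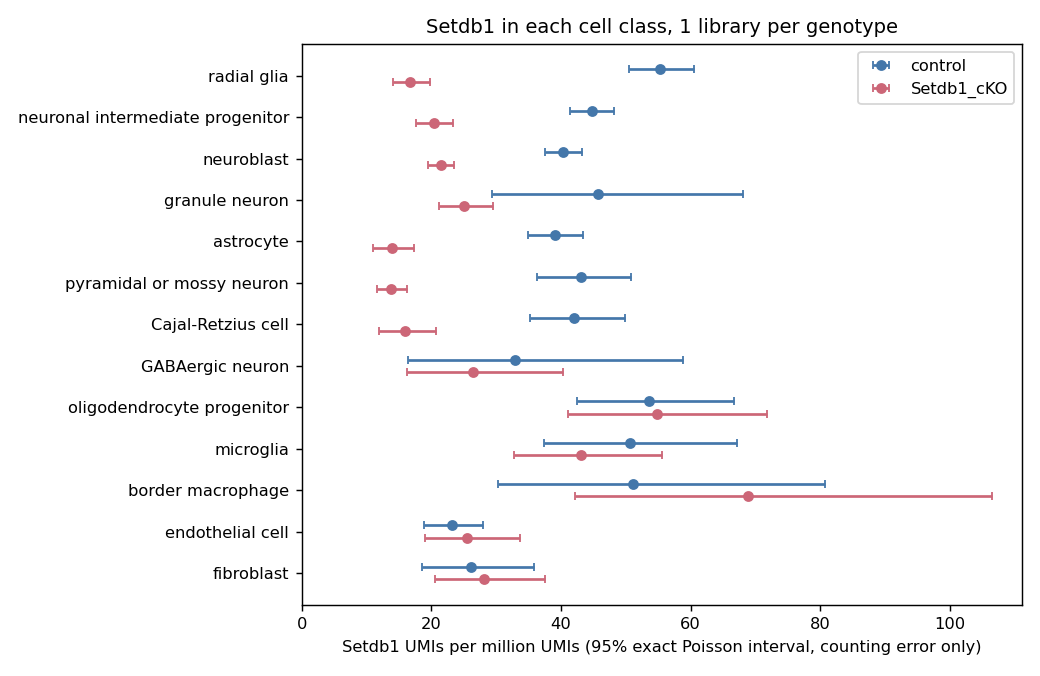
Setdb1 CPM (horizontal axis) in each cell class (vertical axis) of the control and the Setdb1_cKO library, with 95% exact Poisson intervals for counting error only. Radial glia stood at 55.4 in control and 16.7 in Setdb1_cKO, while endothelial cells, fibroblasts and microglia had overlapping intervals.

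The libraries also differed in the sex of the tissue. Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), was at 0.22 CPM in control (16 UMIs) and 1234 CPM in Setdb1_cKO (93954 UMIs). Its antisense gene Tsix was at 0.565 and 107 CPM, and because the genes overlap their reads may be shared. The Y-linked genes went the other way. Ddx3y had 4165 UMIs in control and 0 in Setdb1_cKO, at least 1456-fold lower against a floor of 3 counts over the library, and Eif2s3y had 3914 and 0 UMIs. Kdm5d stood at 20.5 and 0.0394 CPM and Uty at 14.7 and 0.0263 CPM, the last values resting on 3 and 2 UMIs. The 6 sex-linked genes of the fixed list, which holds genes of both directions, had a median log2 ratio of -8.54 in radial glia, or -5.95 with members at 0 set to their bound. Genotype and sex therefore cannot be told apart from these libraries. The median log2 ratio of X-linked genes in radial glia was -0.05 (428 genes) and that of autosomal genes -0.10 (12060 genes).

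The share of cells in each class was compared next, as a description of which cells each library held. Oligodendrocyte progenitors made up 2.98% of control and 1.92% of Setdb1_cKO cells, a ratio of 0.642, and endothelial cells 3.35% and 1.52%, a ratio of 0.453. Cajal-Retzius cells were at 3.97% and 4.19%, fibroblasts at 1.87% and 2.05%, and microglia at 1.27% and 1.65%. None of the measured genes that led the clusters of these 5 classes differed 2-fold or more between the libraries. In the classes that follow, leading genes of the clusters did differ by that much, or, for mural, ependymal and other blood cells, were not compared, so their shares are given as numbers of cells assigned and no direction is drawn from them. Calb1, the calcium-binding protein calbindin and 1 of the 10 leading genes of the granule neuron cluster, was itself at 366 CPM in control and 88.5 CPM in Setdb1_cKO cells of that cluster, a direction that turned to a log2 ratio of 2.499 without 7 control cells that stood in the pyramidal or mossy cluster when each library was clustered alone. The granule neuron cluster held 62 control and 588 Setdb1_cKO cells, 0.574% (0.440 to 0.735) and 6.29% (5.81 to 6.80) of all kept cells, a ratio of 11.0 (8.43 to 14.5). With looser cell filters the ratio was 2.14 (644 and 1177 cells), with stricter filters 21.8 (10 and 171 cells), and with each library clustered alone 0 control cells were named granule neurons.

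Pyramidal or mossy neurons, which surround the dentate gyrus or lie in its hilus, numbered 176 and 534 cells, 1.63% and 5.71%, a ratio of 3.51 (2.95 to 4.18), and 2 of their 10 leading genes differed. GABAergic neurons numbered 36 and 80, a ratio of 2.57 (1.71 to 3.92) that was 1.52 (1.07 to 2.17), on 60 and 79 cells, with each library clustered alone. Astrocytes were assigned 1159 and 652 cells (10.7% and 6.98%), and intermediate progenitors 1975 and 1151 (18.3% and 12.3%). Radial glia were at 13.05% and 11.9% and neuroblasts at 32.7% and 36.1%, ratios of 0.911 and 1.10 whose direction turned with the settings: radial glia came to 1.10 with looser filters, and neuroblasts to 0.609 with stricter ones. Neuroblasts and granule neurons together were at 33.3% and 42.3%, a ratio of 1.27 that became 0.675 with stricter filters. The ratio for astrocytes became 1.41 when each library was clustered alone, where 0 cells of the Setdb1_cKO library were named radial glia and 1806 astrocytes. Of the smaller classes, mural cells were at 0.519% and 0.150%, ependymal cells at 0.167% and 0.770%, border macrophages at 0.676% and 0.589% and other blood cells at 0.574% and 0.963%. Clusters left without a name held 7.30% of control and 6.10% of Setdb1_cKO cells.

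**Figure D2:**
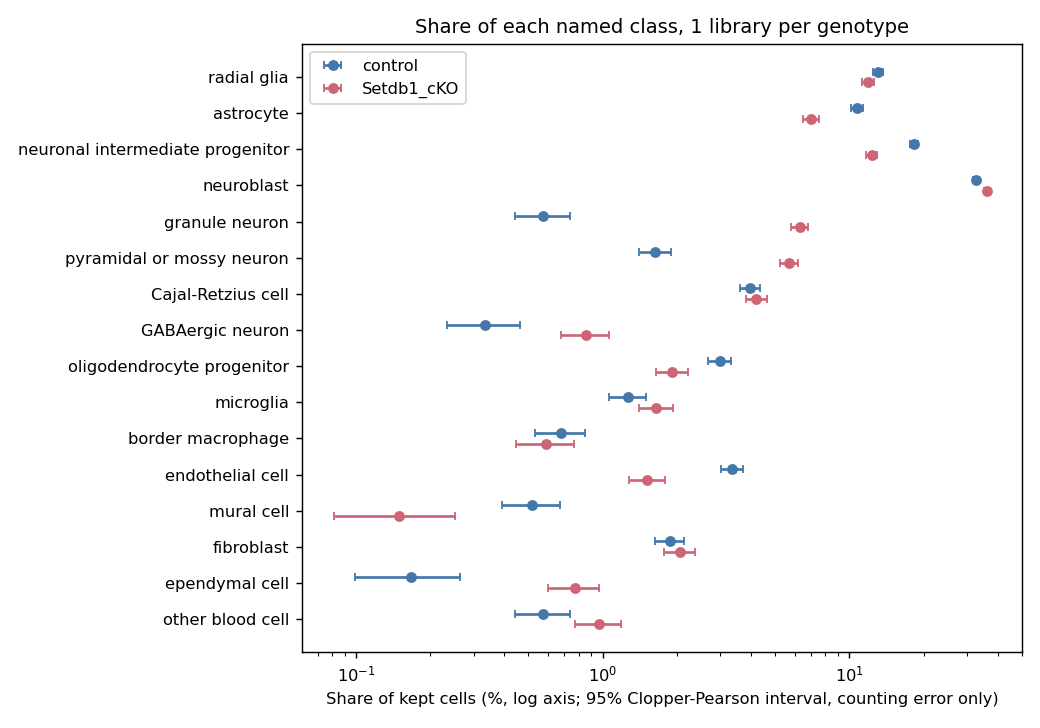
Share of kept cells (percent, log axis) in each named class of the control and the Setdb1_cKO library, with 95% exact Clopper-Pearson intervals for counting error only. Granule neurons stood at 0.574% and 6.29%, and endothelial cells at 3.35% and 1.52%.

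Fewer radial glia of the Setdb1_cKO library, as named by joint clustering, carried RNA of proliferation genes. After each cell was thinned to 2000 UMIs, at least 1 UMI of Top2a or Mki67, genes of dividing cells, was found in 14.3% of control radial glia (200 of 1399, interval 12.5 to 16.2) and 6.49% of Setdb1_cKO radial glia (72 of 1110, 5.11 to 8.10). Among intermediate progenitors the shares were 35.4% (33.2 to 37.5) and 37.9% (35.1 to 40.8), with overlapping intervals. Top2a was also a leading gene of cluster 13 of that class, so its shares may partly reflect how the class was formed. Pyramidal or mossy neurons, which do not divide, gave a background of 1.71% and 1.31% at median depths of 17003 and 18972 UMIs, against 5700 and 6994 UMIs in radial glia. Granule neurons had 0 of 62 control cells with a UMI, with an exact upper bound of 5.78% for the share of cells with a UMI, and 0.680% of Setdb1_cKO cells. Oligodendrocyte progenitors were at 29.97% and 22.9%, microglia at 19.7% and 12.99%, astrocytes at 3.46% and 2.30%, neuroblasts at 1.32% and 0.719% and Cajal-Retzius cells at 1.25% and 2.15%. Cells under 2000 UMIs were left out, 10 and 1 among radial glia and 18 and 8 among intermediate progenitors. With at least 3 UMIs of the G2/M list as the criterion, the shares in radial glia were 69.2% and 64.4%. Without thinning the shares were 21.4% and 11.2% in radial glia and 46.8% and 49.8% in intermediate progenitors. With looser filters they were 4.40% and 1.65% in radial glia and 10.9% and 6.82% in intermediate progenitors, and with stricter filters the latter were 39.6% and 31.1%, so the direction in intermediate progenitors turned. The cycling shares were not recomputed at other clustering resolutions or without cell cycle genes in clustering. They depend on which cycling clusters were named radial glia, and the cycling cluster so named held 268 control and 83 Setdb1_cKO cells.

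The main classes were radial glia, intermediate progenitors, neuroblasts, granule neurons and astrocytes. In all 5 of them, 11 genes outside the fixed list of sex-linked genes were at least 2-fold higher in the Setdb1_cKO library. Outside that list 0 genes were at least 2-fold lower in all 5. The minimum of 30 UMIs favoured higher genes in granule neurons, where control had 524086 and Setdb1_cKO 5776758 UMIs. Kdm5d, for example, had 1487 and 3 UMIs over all kept cells but 11 and 0 in granule neurons, too few to count. With the sex-linked list counted, Xist and Tsix made 13 higher genes, and Ddx3y and Eif2s3y were the 2 lower ones. Mnd1, which acts in meiotic recombination (chromosome 3, 84087933 to 84155786), was at 9.09 CPM in control and 211 CPM in Setdb1_cKO radial glia, a ratio of 23.3 (18.5 to 29.6). It reached 37.5 (25.7 to 56.8) in astrocytes and 43.7 (12.1 to 361) in granule neurons, the latter on 2 control UMIs. Tcfl5, a transcription factor of male germ cells, had ratios of 16.0 (12.7 to 20.3) in radial glia and 62.0 in astrocytes. Atf7ip, a binding partner of Setdb1 protein (chromosome 6, 136506167 to 136610862), was at 80.4 and 194 CPM in radial glia, a ratio of 2.42 (2.21 to 2.65), and at 2.69 (2.57 to 2.82) in neuroblasts. Crlf2, a cytokine receptor subunit, was at 5.29 (3.99 to 7.12) and Samd1, a chromatin protein, at 3.30 (2.52 to 4.35) in radial glia. Pcdhga12, a clustered protocadherin, was at 3.89 (3.06 to 5.01). The noncoding RNAs and predicted genes gave larger ratios. In radial glia Gm7967 was at 55.2 (40.1 to 78.2), Gm48619 at 447 (152 to 2169, 3 control UMIs), Gm49795 (chromosome 17, 27353861 to 27354668) at 521 (144 to 4306, 2 control UMIs) and 3222401L13Rik (chromosome 18, 37655451 to 37661742) at 9.55 (7.68 to 11.99).

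In astrocytes Gm49795 went from 0 to 520 UMIs, at least 262-fold higher against a floor of 3 counts over the class. In neuroblasts 3222401L13Rik was a leading gene of the clusters that held most Setdb1_cKO cells, so its level there is not an independent result. Gm47283, at 2.66 (2.39 to 2.95) in radial glia, is annotated on chromosome Y (90784738 to 90816464) although Ddx3y was at 0 UMIs in the Setdb1_cKO library, and its reads may be shared with a near-identical copy elsewhere. None of the 11 genes, from which Xist and Tsix were left out, is annotated on chromosome X. The summed level of the 11 genes was 199 CPM in control and 1445 CPM in Setdb1_cKO radial glia, a ratio of 7.28 (6.91 to 7.66), and the ratio was 5.69 in pyramidal or mossy neurons and 3.97 in Cajal-Retzius cells. In the 6 classes in which the Setdb1 interval included 1 it was 2.27 (1.76 to 2.97) in GABAergic neurons, 2.18 in oligodendrocyte progenitors, 1.91 in fibroblasts, 1.81 in endothelial cells, 1.42 in border macrophages and 1.22 (1.003 to 1.49) in microglia. Atf7ip was at 2.16 (1.57 to 2.999) in fibroblasts, 1.38 (0.891 to 2.22) in GABAergic neurons, 1.33 (1.05 to 1.67) in oligodendrocyte progenitors, 1.21 (0.997 to 1.46) in endothelial cells, 1.09 (0.762 to 1.58) in microglia and 0.662 (0.299 to 1.40) in border macrophages. Mnd1 was at 28.6 (7.37 to 245, 2 control UMIs) in oligodendrocyte progenitors, 16.8 (2.85 to 679.98, 1 control UMI) in GABAergic neurons, 5.11 (3.30 to 8.07) in endothelial cells and 3.02 (1.07 to 10.5) in fibroblasts, and its interval included 1 in microglia and border macrophages. After thinning to 2000 UMIs, Mnd1 was detected in 1.36% of control and 34.8% of Setdb1_cKO radial glia, in 0.519% and 20.4% of astrocytes, in 1.195% and 8.04% of endothelial cells, in 0 of 194 control and 1.06% of Setdb1_cKO fibroblasts, and in 0.730% and 1.30% of microglia at median depths of 6196 and 8297 UMIs. The number of shared genes lay between 10 and 14 over the alternatives.

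**Figure D3:**
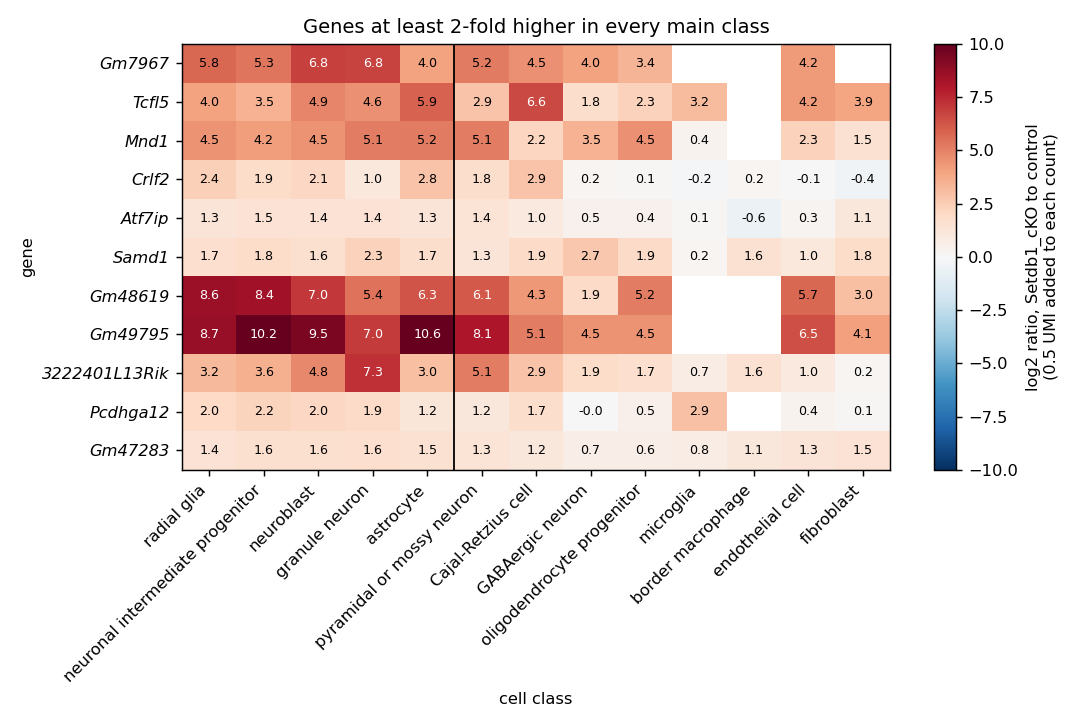
Log2 ratio of Setdb1_cKO to control, with 0.5 UMI added to each count, for the 11 genes (vertical axis) at least 2-fold higher in each of the 5 main classes left of the line, and in 8 other classes (horizontal axis). Blank cells had at most 3 UMIs in both libraries, and Atf7ip stood at a ratio of 2.42 in radial glia, 2.16 in fibroblasts and 1.09 in microglia.

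Germline genes, which are silent in most somatic cells, had more UMIs in the Setdb1_cKO library in each main class. Summed over all 34 listed genes with no minimum of UMIs, they were at 6.96 CPM in control (59 UMIs) and 59.9 CPM in Setdb1_cKO (483 UMIs) radial glia, a ratio of 8.60 (6.56 to 11.5). This ratio was 16.2 (12.96 to 20.6) in intermediate progenitors, 6.30 (5.43 to 7.34) in neuroblasts, 4.93 (3.75 to 6.54) in astrocytes and 1.86 (1.21 to 2.998) in granule neurons, the last on 22 control UMIs. Pyramidal or mossy neurons were at 3.21 (2.49 to 4.20) and Cajal-Retzius cells, where Setdb1 was also lower, at 1.70 (1.42 to 2.04). In classes whose Setdb1 interval included 1, the germline ratio was 2.13 (1.20 to 3.77) in endothelial cells and 1.38 (1.10 to 1.73) in fibroblasts. Its interval included 1 in oligodendrocyte progenitors (1.37, 0.982 to 1.91), GABAergic neurons, microglia and border macrophages. Without the member of highest level in each class the ratio was 5.94 in radial glia, 10.5 in intermediate progenitors, 4.60 in neuroblasts, 7.41 in astrocytes, 3.74 (1.95 to 8.24) in granule neurons, 5.11 in pyramidal or mossy neurons, 3.33 (2.49 to 4.53) in Cajal-Retzius cells, 2.97 in endothelial cells, 1.95 in fibroblasts and 2.29 (1.40 to 3.80) in oligodendrocyte progenitors, whose interval then lay above 1. Ddx4, an RNA helicase of germ cells, had 2 control and 161 Setdb1_cKO UMIs in radial glia, a ratio of 84.6 (23.0 to 705), and Sycp3, of the meiotic synaptonemal complex, was at 15.8. Only 5 of the 34 genes reached 30 UMIs over both libraries in radial glia, a minimum that genes silent in control pass only where they are high in Setdb1_cKO, so the medians that follow cover a selected part of the list, and no percentile among random lists is given for them. The median log2 ratio was 3.85 in radial glia (5 of 5 members at least 1.5-fold higher), 4.83 in intermediate progenitors (6 of 7), 5.91 in neuroblasts (8 of 9) and 4.23 in astrocytes (3 of 3). With members at 0 set to their bound, the neuroblast median was 4.13. In granule neurons 3 of 5 members were higher and 1 lower, and the median of 3.22 became 0.63 with members at 0 set to their bound, and 0.63 also when genes of 5 UMIs were admitted.

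Clustered protocadherins, cell adhesion proteins of the arrays on chromosome 18, were higher in intermediate progenitors, neuroblasts, granule neurons and pyramidal or mossy neurons. Of 36 members measured in intermediate progenitors 24 were at least 1.5-fold higher and 5 lower, with a median log2 ratio of 1.06 (0.77 to 1.28). In neuroblasts 37 of 53 were higher and 6 lower (median 0.99, 0.83 to 1.10), and in granule neurons 28 of 33 were higher and 1 lower (median 1.38, 1.24 to 2.30), all 3 above every random list. Pcdhgb4 was at 5.18 (3.82 to 7.12) and Pcdhga10 at 4.98 (3.75 to 6.69) in intermediate progenitors, and Pcdhga7 at 4.09 (3.60 to 4.67) in neuroblasts. Pcdhgc3, a constitutively expressed member of the gamma array, went the other way in neuroblasts, from 23.7 to 1.63 CPM, a ratio of 0.0685 (0.0469 to 0.0972). Pyramidal or mossy neurons had a median of 1.08, with 29 of 46 members higher and 6 lower. Cajal-Retzius cells, where Setdb1 was also lower, had a median of -0.22, with 6 of 20 higher and 5 lower. In radial glia 11 of 27 members were higher and 6 lower (median 0.19), and in astrocytes 8 of 26 were higher and 7 lower (median -0.12). Members of the alpha and gamma arrays share their 3' exons, so 3' reads may be split between them and single members are uncertain. The random lists drew genes independently and do not allow for shared reads. Control granule neurons numbered 62 cells. The median moved to 0.98 in radial glia with at least 100 UMIs per gene, to 0.56 in astrocytes with doublets kept, and to 0.47 in granule neurons with looser filters.

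**Figure D4:**
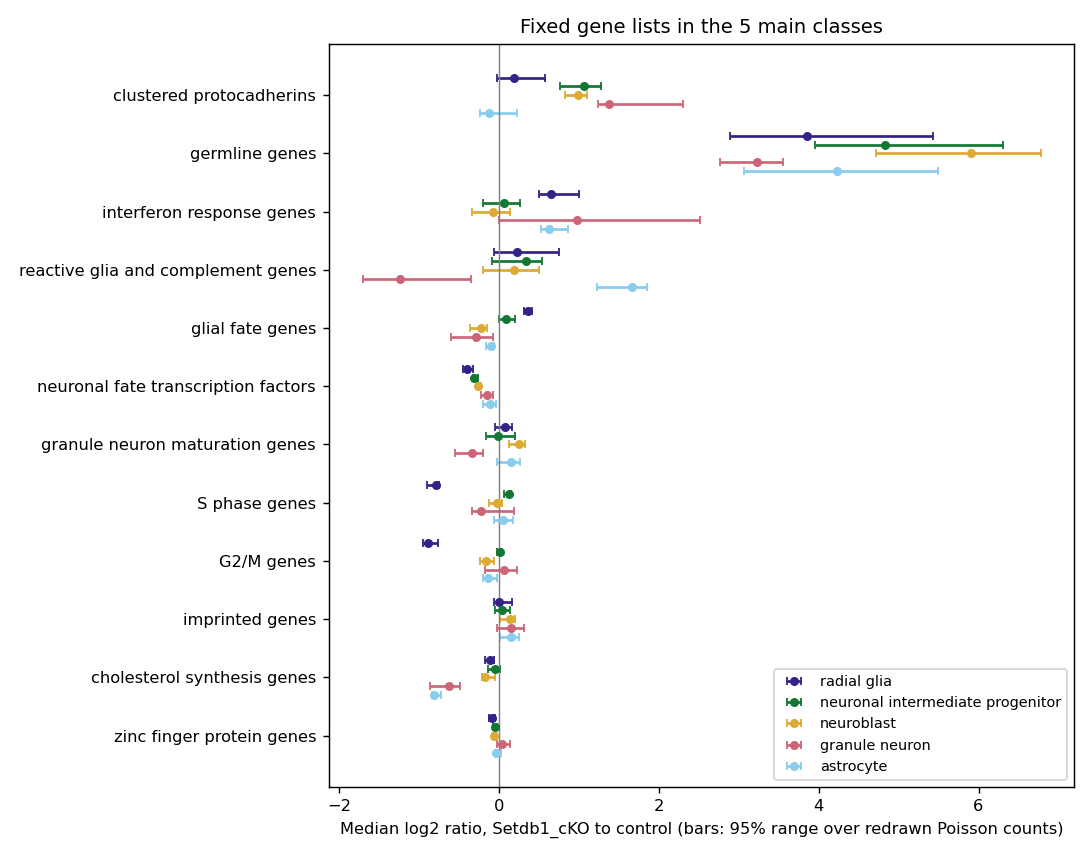
Median log2 ratio of Setdb1_cKO to control (horizontal axis) of 12 fixed gene lists (vertical axis) in the 5 main classes, with bars for the 95% range over redrawn Poisson counts. Germline genes, of which 3 to 9 of 34 passed the minimum of 30 UMIs, lay above 0 in all 5 classes, and S phase and G2/M genes stood apart from 0 in radial glia, at -0.79 and -0.88.

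Radial glia of the Setdb1_cKO library, as named by joint clustering, had more RNA of astrocyte genes and of interferon response genes. They had less of cell cycle and neuronal transcription factor genes. With each library clustered alone, 0 Setdb1_cKO cells were named radial glia and 1806 astrocytes, against 1620 and 1478 control cells. Values within radial glia and within astrocytes therefore depend on the joint naming. Of 18 glial fate genes measured, 8 were at least 1.5-fold higher and 1 lower (median log2 ratio 0.37, 0.32 to 0.41, above all random lists). Gfap, the astrocyte intermediate filament, was at 2.73 (2.63 to 2.84), the water channel Aqp4 at 2.63 (2.48 to 2.79) and S100b at 5.65 (3.63 to 9.14), while Olig1 was at 0.401 (0.252 to 0.623). Of 18 interferon response genes, 10 were higher and 1 lower (median 0.65, 0.50 to 1.01), with Isg15 at 5.44 (3.21 to 9.76), the immunoproteasome subunit Psmb8 at 4.58 (2.53 to 8.87) and B2m at 2.38 (2.03 to 2.80). The median of this list was also 0.30 in endothelial cells and 0.24 in microglia. The glial fate median was between 0.23, with genes of 5 UMIs admitted, and 0.46, with TMM scaling.

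Of 42 S phase genes 35 were at least 1.5-fold lower in Setdb1_cKO radial glia and 0 higher (median -0.79, -0.90 to -0.75), and of 52 G2/M genes 37 were lower and 0 higher (median -0.88, -0.94 to -0.76), below all random lists. The S phase and G2/M medians were also -0.67 and -0.54 in microglia, both below all random lists, -0.18 and -0.10 in oligodendrocyte progenitors, 0.16 and -0.18 in endothelial cells and 0.24 and 0.29 in fibroblasts. Uhrf1 was at 0.407 (0.336 to 0.491), Mcm2 at 0.480 (0.395 to 0.581) and Ube2c at 0.371 (0.314 to 0.436). The cycling radial glia cluster, which S phase genes of this list led, held 268 of 1409 control and 83 of 1111 Setdb1_cKO radial glia. The S phase median moved to -0.24 with looser filters and -0.23 at the lower clustering resolution, and the G2/M median to -0.23 and -0.26. Of 26 neuronal fate transcription factors 9 were lower and 0 higher (median -0.39, -0.45 to -0.32). Eomes, a factor of intermediate progenitors, was at 22.1 and 3.97 CPM (0.180, 0.120 to 0.263). The median of this list was also -0.35 in endothelial cells, -0.35 in oligodendrocyte progenitors and -0.39 in microglia. Among single genes, Wnt8b, a Wnt ligand of the hippocampal primordium, was at 0.207 (0.159 to 0.267), Tmem132c at 0.225 (0.173 to 0.288) and Sparc at 0.316 (0.293 to 0.341). Wnt8b, also a marker used to name radial glia, had a log2 ratio of 3.11 in astrocytes. That value turned to -4.52 with looser filters and -3.00 at the lower clustering resolution. Dcn, a fibroblast marker, was at 0.293 (0.236 to 0.361) in radial glia. On the higher side stood Rnf17, a germ cell gene, at 100 (27.4 to 835, 2 control UMIs), Gm11884 at least 149-fold higher (0 and 424 UMIs), Ptprt at 5.21 (4.03 to 6.82), and the complement gene C4b at 28.0 (9.25 to 139, 3 control UMIs). The 13 mitochondrial genes had a median of 0.50, and their share of UMIs was 3.72% and 4.93%.

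In intermediate progenitors, several germ cell genes were higher in the Setdb1_cKO library and cell cycle genes were nearly level. Ccnb3, a cyclin of meiosis, had 0 and 1006 UMIs, at least 492-fold higher, Tuba3a, a tubulin of the testis, 0 and 323 UMIs, at least 158-fold higher, and Meioc, a meiosis factor, 1 and 416 UMIs, a ratio of 611 (109 to 24177). The S phase median was 0.12 and the G2/M median 0.02, with 0 members 1.5-fold apart in either list, although the S phase median turned to -0.39 with looser filters. Genes of these lists led clusters 10, 13 and 16 of this class, so nearly level medians may partly reflect how the class was formed. Of 29 neuronal fate transcription factors 5 were lower and 1 higher (median -0.31, -0.32 to -0.27). Neurog1 had 46 and 1 UMIs, a ratio of 0.0319 (0.000791 to 0.187). The median of this list moved to -0.08 with looser filters, -0.15 at the lower and -0.14 at the higher clustering resolution. Lower single genes were Dok5, a signalling adaptor, at 0.255 (0.193 to 0.333), the potassium channel Kcnk2 at 0.286 (0.235 to 0.347) and the adrenergic receptor Adra2c at 0.311 (0.258 to 0.372), and the Wnt modulator Sfrp1 was at 0.492 (0.424 to 0.569). The imprinted genes Meg3, at 2.58 (2.35 to 2.83), and Cdkn1c, a cell cycle inhibitor, at 2.83 (2.40 to 3.34), were higher.

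Neuroblasts of the libraries fell into different clusters, so values within this class compare different clusters as well as libraries. Clusters 3 and 5 held 1796 and 1488 control cells but 127 and 109 Setdb1_cKO cells, and clusters 2 and 6 held 141 and 108 control cells but 1848 and 1285 Setdb1_cKO cells. Of the imprinted genes, Meg3 was at 3.40 (3.27 to 3.55), Rian at 3.86 (3.33 to 4.49) and Cdkn1c at 3.17 (2.81 to 3.58), and 6 of 24 members were higher and 1 lower (median 0.15). Ddx4 was at 118 (40.2 to 577, 3 control UMIs), Mov10l1, of the piRNA pathway of germ cells, at least 33.2-fold higher (0 and 108 UMIs) and Sox9, a glial and progenitor factor, at 2.95 (2.59 to 3.38). Lower genes included the splicing regulator Ptbp3 at 0.226 (0.185 to 0.274), Vim at 0.396 (0.347 to 0.450), Eomes at 0.410 (0.357 to 0.470) and the immediate early genes Egr1 at 0.325 (0.278 to 0.380) and Jun at 0.490 (0.459 to 0.524). Of 28 neuronal fate transcription factors 5 were lower and 1 higher (median -0.26). Of 28 granule neuron maturation genes 10 were higher and 2 lower (median 0.25, 0.13 to 0.33), with Dsp at 4.96 (3.62 to 6.92) and the glutamate receptor gene Grin2a at 0.233 (0.162 to 0.329). This median turned to -0.07 with stricter filters and -0.21 at the lower resolution, and was 0.04 with at least 100 UMIs per gene and 0.03 in the early neuroblast clusters alone. Over neuroblasts and granule neurons together, 13 of these genes were higher and 1 lower (median 0.44).

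Granule neurons of the Setdb1_cKO library had less RNA of cholesterol synthesis genes than the 62 control cells, whose sum was 524086 UMIs against 5776758. Lower values of several mature neuron genes rested on 7 of those control cells. Without them the log2 ratios of Grin2a, Hspa2 and Camk2a stayed negative but were smaller in size. No interval is given for these values, so a lower level of these genes without the 7 cells is not established. Of 19 cholesterol synthesis genes 10 were at least 1.5-fold lower and 0 higher (median -0.62, -0.86 to -0.48), among them Msmo1 at 0.439 (0.316 to 0.622) and Insig1 at 0.438 (0.257 to 0.787). Of 27 maturation genes 11 were lower and 1 higher (median -0.33, -0.54 to -0.19), a list that includes Calb1, C1ql3 and Nrgn, leading genes of this cluster. With each library clustered alone, 55 of the 62 control cells stood in a neuroblast cluster and 7, with 20.8% of the UMIs, in the pyramidal or mossy cluster, against 0 of the 588 Setdb1_cKO cells. Without these 7 cells the maturation median was -0.02 and the cholesterol median -0.71. The neurofilament gene Nefl, at a ratio of 0.221 (0.179 to 0.275), Cpne6, at 0.112 (0.0673 to 0.188), Gpr22, at 0.217 (0.159 to 0.301), and Fxyd7, a leading gene of the pyramidal or mossy cluster at 0.0994 (0.0526 to 0.189), came to log2 ratios of 0.02, 2.43, 0.62 and 0.17 without them, so their direction turned. Hspa2 was at 0.0710 (0.0361 to 0.138), Grin2a at 0.179 (0.120 to 0.270) and Camk2a, a synaptic kinase, at 0.414 (0.336 to 0.514), log2 ratios of -3.81, -2.49 and -1.28 that became -0.91, -1.48 and -0.17. The maturation median moved to -0.06 with looser filters and -0.19 when sex-linked, cell cycle and similar genes were kept out of clustering. Sox9 was at 11.8 (3.24 to 98.3, 2 control UMIs), Pcdhb17 at 3.73 (1.87 to 8.71) and Pcdhga7 at 12.1 (4.11 to 58.9, 3 control UMIs). Ribosomal protein genes were higher (18 of 88 higher, 2 lower, median 0.39), and haemoglobin genes, from red blood cells, took 0.000763% of UMIs in control and 0.0437% in Setdb1_cKO granule neurons. TMM and median-of-ratios scaling each raised the median log2 ratio of all measured genes in this class by 0.12, so every log2 ratio here is 0.12 higher under either of them.

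Astrocytes of the Setdb1_cKO library had more RNA of interferon response and reactive glia genes and less of cholesterol synthesis genes. Of 18 interferon response genes 13 were at least 1.5-fold higher and 1 lower (median 0.63, 0.53 to 0.87, above all random lists). The chemokine gene Cxcl10 was at 15.6 (8.64 to 31.1), Psmb8 at 4.54 (2.43 to 8.997), Isg15 at 3.63 (2.54 to 5.26) and Bst2 at 2.36 (1.505 to 3.74). Of 8 reactive glia and complement genes 5 were higher and 0 lower (median 1.66, 1.23 to 1.86), with Lgals3 at 5.34 (3.07 to 9.76), C4b at 3.93 (3.10 to 5.00), the oncostatin M receptor gene Osmr at 3.34 (2.03 to 5.66) and Serpina3n at 3.04 (2.48 to 3.73). The interferon median was 0.14 with stricter filters and 0.47 with doublets kept, and the reactive glia median 0.05 with doublets kept, 0.21 with at least 100 UMIs per gene and 0.67 with stricter filters. The reactive glia median was 0.74 in microglia. Of 20 cholesterol synthesis genes 17 were lower and 0 higher (median -0.81, -0.84 to -0.72), with the sterol carrier gene Stard4 at 0.491 (0.408 to 0.588), and the median was also -0.87 in pyramidal or mossy neurons, -0.92 in microglia, -0.38 in oligodendrocyte progenitors and -0.29 in endothelial cells. In the list of immediate early and heat shock genes 6 of 21 were higher and 2 lower (median 0.22), with Socs3 at 3.93 (3.38 to 4.57), Zfp36 at 3.59 (2.98 to 4.35) and Atf3 at 7.56 (4.13 to 14.96). Haemoglobin genes took 0.00183% and 0.0414% of astrocyte UMIs.

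Other genes that stood out in astrocytes included Olig1, a glial fate list member, at 0.411 (0.378 to 0.447). Azgp1 was at 233 (41.2 to 9259.8, 1 control UMI), on chromosome 5 at 137981520 to 137990233. On the lower side were the scaffold gene Akap12 at 0.138 (0.103 to 0.182), Emid1 at 0.215 (0.182 to 0.254), Igfbp2, a growth factor binding protein, at 0.286 (0.266 to 0.307), and Kcnmb4 at 0.335 (0.287 to 0.389).

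The remaining lists are given as values. Over the 5 main classes, H3K9 methylation and partner genes had medians between -0.15 in radial glia and 0.12 in intermediate progenitors, and p53 target genes between -0.08 in neuroblasts and 0.11 in astrocytes. In other classes the former list was at -0.22 in microglia, and the latter at -0.17 in pyramidal or mossy neurons, 0.15 in Cajal-Retzius cells and 0.19 in GABAergic neurons. Zinc finger protein genes, many of which bind the machinery that recruits Setdb1, had a median of -0.09 in radial glia, where 24 of 321 were at least 1.5-fold higher and 17 lower. Zfp992 was at 13.9 (7.08 to 31.1) and Zfp809, a repressor of retroviruses, at 3.24 (2.47 to 4.31). Wnt and Shh signalling genes had a median of -0.27 in radial glia (2 of 19 higher, 6 lower), and quiescence and niche signalling genes of 0.11 (5 of 24 higher, 0 lower), at percentiles of 0.490 and 99.9 among random lists. Unfolded protein and integrated stress response genes were at -0.02 in radial glia and 0.54 in pyramidal or mossy neurons.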

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

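The tests of a sex difference, of the share on the X chromosome with Xist and Tsix counted, of dissection, of pyramidal neurons under separate clustering and of microglial RNA by level, the renaming of a control cluster and the value without 7 control granule neurons, which stood in the pyramidal or mossy cluster under separate clustering, were chosen only after the results were seen. The list medians given next stood on opposite sides of 0 in different classes, and these differences between classes were not tested. Immediate early and heat shock genes had a median log2 ratio of 0.22 in astrocytes and -0.30 in neuroblasts. Glial fate genes were at 0.37 in radial glia and -0.22 in neuroblasts. Granule neuron maturation genes were at 0.25 in neuroblasts and -0.33 in granule neurons, the latter -0.02 without 7 control cells. Haemoglobin genes were at 5.16 in granule neurons and -2.98 in intermediate progenitors. Reactive glia and complement genes were at 1.66 in astrocytes and -1.23 in granule neurons, where 3 members were measured. Xist, outside the comparison of genotypes, stood at 1234 CPM in the Setdb1_cKO library.

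The 11 genes higher in every main class were weighed first. Dosage of a gene's own X-linked copies was excluded as the cause of most of them, as 15.4% are annotated on chromosome X even with Xist and Tsix counted. The location of a gene cannot test effects of X dosage on other chromosomes. In endothelial cells, fibroblasts and microglia pooled, where each Setdb1 interval included 1, the autosomal members still had a median log2 ratio of 1.32 (1.04 to 1.71). All 11 genes had a median of 3.25 (2.95 to 3.59) in radial glia, so the excess was smaller in the pooled classes. The ratio of the summed autosomal members there was 1.46 (1.34 to 1.60). A sex difference may account for part of the pattern, but other sources of the excess in these classes were not examined. Sex cannot be told apart from genotype, because 1 library is male and 1 female by Xist and Ddx3y. Loss of Setdb1 remains the biological hypothesis that the design names, untested against sex.

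The larger numbers of cells assigned to granule and pyramidal neurons in the Setdb1_cKO library were weighed next. GABAergic neurons, which do not arise from dentate progenitors, had a ratio of 2.57 (1.71 to 3.92), or 1.52 (1.07 to 2.17) with each library clustered alone, but 1 leading gene of their cluster differed at least 2-fold between the libraries, so no direction was drawn from it and dissection or recovery was not decided. For pyramidal or mossy neurons the ratio was 2.32 (2.002 to 2.70) with each library clustered alone. A larger share was thus assigned without joint clustering too. That interval covers counting error only, and the naming of the separate clusters was not varied for this class, so an effect of naming stays open. For granule neurons joint clustering stays open: 0 control cells were named so when that library was clustered alone, a ratio of at least 209.9, yet 55 of the 62 then stood in a neuroblast cluster of 571 cells and 7 in the pyramidal or mossy cluster, and the ratio was 1.10 (0.979 to 1.24) with that cluster counted as granule neurons, so a limit of 2 could not decide. Dissection thus remains a possible explanation, and no direction of differentiation is drawn from these shares.

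The higher interferon response genes in Setdb1_cKO astrocytes were the last pattern weighed. The small Gfap-rich astrocyte cluster was excluded as the whole cause, since the median log2 ratio was 0.58 (0.43 to 0.78) without it. Microglial RNA, read from the level of the C1q genes, would give 0.358% of the excess and was excluded as the main source. Sex and genotype stay open for this pattern, and it may rest on either.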

How the results depend on the processing

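Each library clustered alone, the early and late neuroblast clusters, astrocytes without the Gfap-rich cluster, granule neurons without 7 control cells named pyramidal or mossy neurons under separate clustering, and the denominator without unnamed clusters were alternatives chosen only after the data had been seen. No paired analysis was possible because each genotype has 1 library. The Setdb1 ratio stayed below 1 in each of the 5 main classes under all 35 alternative values, at 0.303 to 0.332 in radial glia, 0.291 to 0.403 in astrocytes, 0.410 to 0.468 in intermediate progenitors, 0.519 to 0.576 in neuroblasts and 0.449 to 0.596 in granule neurons. The number of genes higher in every main class was 10 to 14. Crlf2 was lost when each cell was scaled on its own and Pcdhga12 with looser and with stricter filters, while Adk, Cep112, Dand5 or Rnf17 were added in some settings. Germline medians stayed above 0 in all 5 classes (lowest 0.63, in granule neurons), interferon medians in radial glia (0.58 to 0.96) and astrocytes (0.14 to 0.66), and cholesterol medians below 0 in astrocytes (-0.82 to -0.60) and granule neurons (-0.73 to -0.50). The S phase and G2/M medians stayed below 0 in radial glia. A value counted as turned only where the main interval excluded no change, so the protocadherin median in astrocytes, -0.12 in the main setting and 0.56 with doublets kept, counted as moved. Of 287 alternative values of the lists that the comparisons lead with, 221 stayed within counting error, 64 moved and 2 turned, and of 855 for other lists these numbers were 723, 117 and 15. For 324 named genes, 3130 of 3426 values stayed, 276 moved and 20 turned. Of 62 ratios of shares 30 stayed, 21 moved and 11 turned, and of 24 cycling shares 5 stayed and 19 moved. The cycling shares were not recomputed at other clustering resolutions or without cell cycle genes in clustering. Granule neurons and radial glia had no ratio beyond a bound with each library clustered alone, since 1 library had 0 such cells. Unnamed clusters held up to 13.4% of control cells, with looser filters, and 28.0% of Setdb1_cKO cells, with stricter ones. Among the 5 main classes, granule neurons had the fewest UMIs in control, from 62 cells. The values that moved beyond counting error or turned follow by setting, with the list of each median in parentheses, and the cause was not tested.

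With looser filters, the ratio of shares turned to 1.10 for radial glia and 0.990 for neuroblasts. Looser filters moved the ratio of shares to 0.946 for intermediate progenitors, 2.14 for granule neurons, 0.565 for astrocytes, 2.63 for pyramidal or mossy neurons and 1.15 for neuroblasts with granule neurons. Looser filters gave cycling shares of 4.40% in control radial glia, 1.65% in Setdb1_cKO radial glia, 10.9% in control intermediate progenitors and 6.82% in Setdb1_cKO intermediate progenitors. Looser filters turned the log2 ratio to 0.45 for Nusap1 in radial glia, -1.06 for Rspo3 in intermediate progenitors, -1.56 for Rspo2 in astrocytes and -4.52 for Wnt8b in astrocytes. Looser filters turned the list medians to -0.0222 (H3K9 genes), -0.39 (S phase) and -0.0912 (quiescence) in intermediate progenitors. Looser filters moved the list medians to -0.24 (S phase), -0.23 (G2/M) and 0.32 (glial fate) in radial glia, -0.0777 (neuronal factors) in intermediate progenitors, -0.30 (neuronal factors) in neuroblasts, 0.47 (protocadherins), 4.01 (germline) and -0.0551 (maturation) in granule neurons and 1.08 (reactive glia) in astrocytes. With stricter filters, the ratio of shares turned to 0.609 for neuroblasts and 0.675 for neuroblasts with granule neurons. Stricter filters moved the ratio of shares to 0.661 for radial glia, 0.827 for intermediate progenitors, 21.8 for granule neurons, 0.565 for astrocytes and 2.94 for pyramidal or mossy neurons. Stricter filters gave cycling shares of 8.10% in Setdb1_cKO radial glia, 39.6% in control intermediate progenitors and 31.1% in Setdb1_cKO intermediate progenitors. Stricter filters turned the log2 ratio to -0.14 for Zfp110 in granule neurons. Stricter filters turned the list medians to 0.00422 (cholesterol) in radial glia, -0.15 (S phase) in intermediate progenitors and -0.0657 (maturation) and 0.00793 (zinc fingers) in neuroblasts. Stricter filters moved the list medians to -0.63 (S phase) and -0.47 (G2/M) in radial glia, 1.33 (protocadherins) and -0.21 (neuronal factors) in intermediate progenitors, 2.19 (germline) in granule neurons and 0.14 (interferon), -0.60 (cholesterol) and 0.67 (reactive glia) in astrocytes. With doublets kept, the ratio of shares moved to 0.722 for astrocytes and 2.70 for pyramidal or mossy neurons. Kept doublets gave cycling shares of 40.9% in Setdb1_cKO intermediate progenitors. Kept doublets turned the list medians to 0.0669 (neuronal factors) in astrocytes. Kept doublets moved the list medians to -0.74 (S phase), -0.96 (G2/M) and 0.25 (glial fate) in radial glia, -0.33 (neuronal factors) in intermediate progenitors and 0.56 (protocadherins), 3.06 (germline), 0.47 (interferon) and 0.0540 (reactive glia) in astrocytes.

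At resolution 0.6, the ratio of shares turned to 1.08 for radial glia and 0.524 for neuroblasts. Resolution 0.6 moved the ratio of shares to 0.764 for intermediate progenitors, 2.55 for pyramidal or mossy neurons and 1.16 for neuroblasts with granule neurons. Resolution 0.6 turned the log2 ratio to 0.42 for Nusap1 in radial glia, -0.54 for C1ql3 in neuroblasts, -0.45 for C1ql2 in neuroblasts, -0.83 for Plk5 in neuroblasts, -0.88 for Rspo2 in astrocytes and -3.00 for Wnt8b in astrocytes. Resolution 0.6 turned the list medians to -0.0867 (S phase) and 0.00817 (zinc fingers) in intermediate progenitors and -0.21 (maturation) and 0.0304 (quiescence) in neuroblasts. Resolution 0.6 moved the list medians to -0.23 (S phase) and -0.26 (G2/M) in radial glia, 1.29 (protocadherins) and -0.15 (neuronal factors) in intermediate progenitors, 0.82 (protocadherins) and -0.17 (neuronal factors) in neuroblasts and 0.49 (interferon) in astrocytes. At resolution 2.0, the ratio of shares turned to 0.977 for neuroblasts. Resolution 2.0 moved the ratio of shares to 0.918 for intermediate progenitors and 1.13 for neuroblasts with granule neurons. Resolution 2.0 turned the log2 ratio to 0.00543 for Zfp385b in intermediate progenitors. Resolution 2.0 turned the list medians to -0.21 (S phase) in intermediate progenitors. Resolution 2.0 moved the list medians to -0.71 (S phase) and 0.27 (glial fate) in radial glia, -0.14 (neuronal factors) in intermediate progenitors and -0.30 (neuronal factors) in neuroblasts. Without the sex-linked, cell cycle and similar genes in clustering, the ratio of shares turned to 0.802 for neuroblasts. This gene choice moved the ratio of shares to 2.56 for pyramidal or mossy neurons. This gene choice moved the list medians to -1.05 (G2/M), 0.24 (glial fate) and -0.30 (neuronal factors) in radial glia, 0.77 (protocadherins) and 0.0941 (maturation) in neuroblasts and 1.10 (protocadherins) and -0.19 (maturation) in granule neurons. With each library clustered alone, the ratio of shares turned to 0.637 for neuroblasts, 1.41 for astrocytes and 0.797 for neuroblasts with granule neurons. Separate clustering moved the ratio of shares to 0.966 for intermediate progenitors, 2.32 for pyramidal or mossy neurons and 1.52 for GABAergic neurons.

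With TMM factors, list medians turned to 0.0109 (zinc fingers) in radial glia. TMM factors moved the list medians to -0.69 (S phase), 0.46 (glial fate) and -0.30 (neuronal factors) in radial glia and -0.22 (neuronal factors) in neuroblasts. With the median-of-ratios factor, list medians moved to -0.71 (S phase), 0.44 (glial fate) and -0.32 (neuronal factors) in radial glia and -0.20 (neuronal factors) in neuroblasts. With totals free of mitochondrial, haemoglobin and ribosomal protein genes, list medians moved to -0.21 (neuronal factors) in neuroblasts. With each cell scaled on its own, list medians moved to -0.98 (G2/M) in radial glia. With genes of 5 UMIs admitted, list medians moved to 0.23 (glial fate) in radial glia, 4.19 (germline) in neuroblasts, 0.63 (germline) in granule neurons and 1.15 (reactive glia) in astrocytes. With 100 UMIs required, list medians moved to 0.98 (protocadherins) in radial glia, 1.44 (protocadherins) in intermediate progenitors, 0.0436 (maturation) in neuroblasts and 0.21 (reactive glia) in astrocytes. Thinned to 1000 UMIs, the cycling share was 9.79% in control radial glia, 29.1% in control intermediate progenitors and 29.4% in Setdb1_cKO intermediate progenitors. Unthinned, the cycling share was 21.4% in control radial glia, 11.2% in Setdb1_cKO radial glia, 46.8% in control intermediate progenitors and 49.8% in Setdb1_cKO intermediate progenitors. With at least 3 UMIs of the G2/M list as the criterion, the cycling share was 69.2% in control radial glia, 64.4% in Setdb1_cKO radial glia, 79.3% in control intermediate progenitors and 81.4% in Setdb1_cKO intermediate progenitors. In early neuroblast clusters alone, the log2 ratio turned to -0.21 for Plk5. Early clusters turned the list medians to 0.0383 (G2/M) and 0.0286 (quiescence). Early clusters moved the list medians to 0.0344 (maturation). In late neuroblast clusters alone, the log2 ratio turned to 0.20 for H2-K1. Late clusters turned the list medians to -0.0122 (H3K9 genes). Late clusters moved the list medians to -0.29 (neuronal factors). Without the 7 control granule neurons of the pyramidal cluster, the log2 ratio turned to 2.43 for Cpne6, 0.17 for Fxyd7, 0.0158 for Nefl, 2.499 for Calb1, 0.62 for Gpr22 and 0.15 for Klf9. Leaving out these cells moved the list medians to -0.0163 (maturation) in granule neurons.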

Other observations

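The tests of Mnd1 in cells of control-like clusters and of Setdb1 against control cells of the same clusters were chosen only after the results were seen. Pyramidal or mossy neurons of the Setdb1_cKO library differed in more lists than those described so far. The 7 measured germline genes had a median log2 ratio of 0.77 (0.62 to 2.65). Ribosomal protein genes were at 0.70 and unfolded protein and integrated stress response genes at 0.54 (0.44 to 0.68), both above all random lists. Quiescence and niche signalling genes were at -0.90 (-1.10 to -0.60) and glial fate genes at -0.97 (-1.07 to -0.55), both below all random lists. Haemoglobin genes were at 4.70 (4.13 to 5.50), above all random lists, and took 0.00135% of UMIs in control and 0.0261% in Setdb1_cKO cells, a ratio of 19.3 (14.3 to 26.6). Mnd1 was at 35.9 (24.8 to 54.1) in this class.

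Cajal-Retzius cells had higher medians of unfolded protein and integrated stress response genes, at 0.46 (0.31 to 0.62), and of immediate early and heat shock genes, at 0.37 (0.09 to 0.70), both above all random lists. Atf7ip was at a ratio of 1.99 (1.73 to 2.29) and Mnd1 at 4.56 (3.06 to 6.999) in them. In microglia haemoglobin genes were at -9.14. After thinning, Tcfl5 was detected in 1.501% of control and 23.7% of Setdb1_cKO radial glia, in 0 of 251 control and 3.57% of Setdb1_cKO endothelial cells, and in 0 of 137 control and 1.95% of Setdb1_cKO microglia.

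In the Setdb1_cKO library 236 neuroblasts fell into the clusters that held most control neuroblasts, against 3133 in the other neuroblast clusters, and a hypothesis was that these cells might have kept Setdb1. Setdb1 was at 21.7 CPM in them, on 26 UMIs, against 39.9 CPM in the 3284 control cells of the same clusters, a ratio of 0.543 (0.352 to 0.802), which excluded that all of them had control levels of Setdb1. Against the other neuroblasts of their library the ratio was 1.01 (0.653 to 1.503), so a smaller part with Setdb1 stays open at this depth. Mnd1 and Tcfl5 were at ratios of 1.04 (0.900 to 1.20) and 1.08 (0.840 to 1.37) to those neuroblasts. Against control cells of the same clusters they were at 23.3 (18.7 to 29.2) and 30.9 (20.4 to 47.7). Cells with Setdb1 would lie lower if they resembled endothelial cells, where Mnd1 was at 5.11 (3.30 to 8.07) between the libraries against 22.0 in neuroblasts. Judged by the ratio between the libraries, they would not if they resembled oligodendrocyte progenitors, whose Setdb1 interval included 1. Mnd1 was at 28.6 (7.37 to 245) in those progenitors, a ratio that rests on few control UMIs. Compared by ratio, Mnd1 did not decide it, and its CPM in those progenitors was not compared with that in neuroblasts.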
